A study of Mus musculus with 16 samples.

How the data were processed

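RNA from 16 mouse pluripotent stem cell lines was hybridised to 16 single-colour Agilent arrays, 4 lines in each of 4 culture groups, LIF_serum, EpiSC, 2i_LIF and 2iSB_LIF. Groups, line numbers and passage numbers were taken from the labels. The arrays lay on 2 slides scanned on 2 days. Slide 1 held LIF_serum arrays 1 and 2, 2i_LIF arrays 1, 2 and 3 and 2iSB_LIF arrays 1, 2 and 4, and slide 2 held the others. The number of arrays limits the precision of every comparison.

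Per the file headers, the scanner files hold intensity values written by Agilent Feature Extraction 10.7.1.1, and the processed signal used here is background-subtracted and spatially detrended, with no normalization between arrays. The authors also deposited a single table of log2 values, per the labels made with limma and Feature Extraction. Its normalization method is not given in the sources used here, and its log base was read from its values. It holds 42316 of the 55681 probes and leaves out 13365. Its columns share the same highest value, 18.90, and their medians are 7.56, 7.56, 7.54 and 7.54 in LIF_serum, 7.51, 7.52, 7.52 and 7.52 in EpiSC, 7.57, 7.58, 7.56 and 7.55 in 2i_LIF, and 7.57, 7.56, 7.56 and 7.56 in 2iSB_LIF, in array order. No column was left unmapped, so the direction of each comparison is known from the labels. The absolute scale of the values, and whether total messenger RNA per cell differs between groups, stay unknown.

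Each array has 62976 spots, of which 3671 are controls. Probes were named through the RefSeq accession in the files and a reference table of the GRCm38 annotation, since the files used here give no gene symbols, while the array header names build mm9. In all 27656 probes matched 1 of 20972 gene symbols, none matched several, 16194 were named only by genome position and 11831 others had no match. Probes of gene families with near-identical members, such as Zscan4, Rhox, Tuba3, Fthl17 and Duxbl, may measure several members. Spots marked as outliers by Feature Extraction, 100 to 321 per array, were treated as missing, and 432 probes with several spots were averaged.

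Values are log2 of the processed signal less the array's 75th percentile. A probe was tested if it was well above background on all 4 arrays of at least 1 group, and the probe of highest mean signal stood for its gene, which left 15506 genes. Well above background was taken from the scanner software, and 51.6% to 63.9% of probes passed per array. The 75th percentile of the processed signal was 646 on 2i_LIF array 4 and 1039 on 2i_LIF array 2, the lowest and highest of the arrays. A linear model of 4 group means over all 16 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with data.table (1.17.8) and jsonlite (2.0.0) for reading files. Adjusted p-values are Benjamini-Hochberg values within a comparison. A gene was called at an adjusted p under 0.05 and a difference of at least 2-fold. A gene well above background on all arrays of the brighter group and on none of the dimmer group is given as a bound, the difference from the background floor of the dimmer arrays, or from their signal where that was higher. The floor is the lowest signal well above background on an array and lies between −6.17 and −4.67 on the log2 scale. A bound, given as at least so many fold, holds for this background subtraction only. With another background correction, normexp, medians of several lists were smaller than at the bounds. Many other called list members were well above background on only some arrays of the dimmer group. Their differences are given as measured, and for Fgf5 and Sycp3 a bound with the dim arrays held at the floor was added after the results had been seen.

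The genes named as largest changes had to be called, with every array of one group above every array of the other, and to carry a gene symbol that is not a clone or predicted name. They are the 10 largest rises and falls of each of the first 4 comparisons among genes well above background on all arrays of both groups, and the 3 rises and falls with the largest bound. For the last 2 comparisons they are 5 and 2. Members of the fixed lists may be named besides. A result that this rule selects between 2iSB_LIF and 2i_LIF is not reported here.

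The 26 lists, with 406 memberships of which 383 were tested, were tested with limma's camera at its preset correlation, and again with a correlation estimated for each list. They are naive pluripotency, core pluripotency, primed epiblast, primitive streak and mesendoderm, primitive endoderm, neural ectoderm, trophectoderm, 2-cell-like, ERK feedback, Wnt/beta-catenin, Nodal/Activin, BMP and LIF/STAT3 targets, DNA methylation enzymes, germline genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, Myc and ribosome biogenesis, cell cycle inhibitors and p53 targets, Hox genes, imprinted genes, epithelial, mesenchymal and fibroblast genes, and a list of sex chromosome genes read per array without camera. Several lists share members. In the sex chromosome list Kdm5d, Uty and Xist did not pass the filter on signal, and Uty and Xist are given as measured.

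The groups, comparisons, test, thresholds, lists, rule for naming genes and most alternatives were chosen before the data were examined. The alternatives were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' table, other filters and thresholds, slide, line number or passage in the fit, single slides, only the 8 arrays compared, other ways to join probes, another variance model, array weights and leaving out each array in turn. Normexp was planned on the mean spot signal, which the files do not hold, and used the median spot signal and median local background. Array weights were fitted gene by gene because the planned method did not converge, a change made after its counts had been seen. Comparisons with only LIF_serum arrays 3 and 4 or only arrays 1 and 2, without X- and Y-linked genes, and without genes higher on LIF_serum arrays 1 and 2 were added after the data had been seen.

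The procedure was tested on simulated data with the means and residual spread of the real genes, in which 100 genes per comparison and size were given a difference. At a log2 difference of 1.5 between 67 and 77 of them were recovered, at 3 between 93 and 96, and between 3 and 11 unchanged genes were called. The simulated noise was independent between genes, with no slide difference and no background floor, and most genes were unchanged. The rates therefore need not hold for the real arrays. Probes named only by genome position were counted but not interpreted. Of 4047 genes with several tested probes, 25 or fewer per comparison had probes called in opposite directions. Among those with a call, all probes were called one way for 734 of 1668 between EpiSC and LIF_serum. Against LIF_serum this held for 345 of 861 in 2i_LIF and 405 of 912 in 2iSB_LIF. Against EpiSC it held for 922 of 1704 and 918 of 1656, and between 2iSB_LIF and 2i_LIF for 3 of 8.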

Results

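Messenger RNA levels were measured on 16 single-colour Agilent mouse arrays, 1 array for each of 16 pluripotent stem cell lines of one mouse strain. The labels put 4 lines in each of 4 groups. LIF_serum lines came from pre-implantation embryos, were kept in serum with the cytokine LIF, and are called naive in the labels. EpiSC lines came from the epiblast of post-implantation embryos, were kept in Activin A and bFGF, and are called primed. The 2i_LIF and 2iSB_LIF lines came from pre-implantation embryos and are called ground state. Both were kept with LIF and inhibitors of the kinases MEK and GSK3, and 2iSB_LIF lines also received an inhibitor of the receptors for Activin, Nodal and TGF-beta. Between 51.6% (LIF_serum array 3) and 63.9% (2iSB_LIF array 4) of probes were well above background, and no probe was saturated. The number of arrays, 4 per group, limits the precision of every value.

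EpiSC, LIF_serum and ground-state arrays lay apart from each other, while 2i_LIF and 2iSB_LIF arrays intermixed. The mean correlation was 0.973 between 2i_LIF and 2iSB_LIF arrays, 0.971 within 2i_LIF and 0.974 within 2iSB_LIF. The first principal component of the tested genes with no missing value on any array held 66.5% of the variance and separated EpiSC arrays from the rest. The second held 14.3% and separated LIF_serum from the ground-state arrays. Correlations between arrays of 1 group were at least 0.962 in 2i_LIF and 0.956 in 2iSB_LIF and LIF_serum, and higher in EpiSC. Arrays lay on 2 slides, with all EpiSC arrays on slide 2 and the other groups divided between them. LIF_serum arrays 1 and 2 (slide 1) correlated at 0.991 with each other, and arrays 3 and 4 (slide 2) at 0.995. The descriptions of arrays 1 and 2 carry the code LS and those of arrays 3 and 4 the code LSFF, whose meaning the labels do not give.

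**Figure D1:**
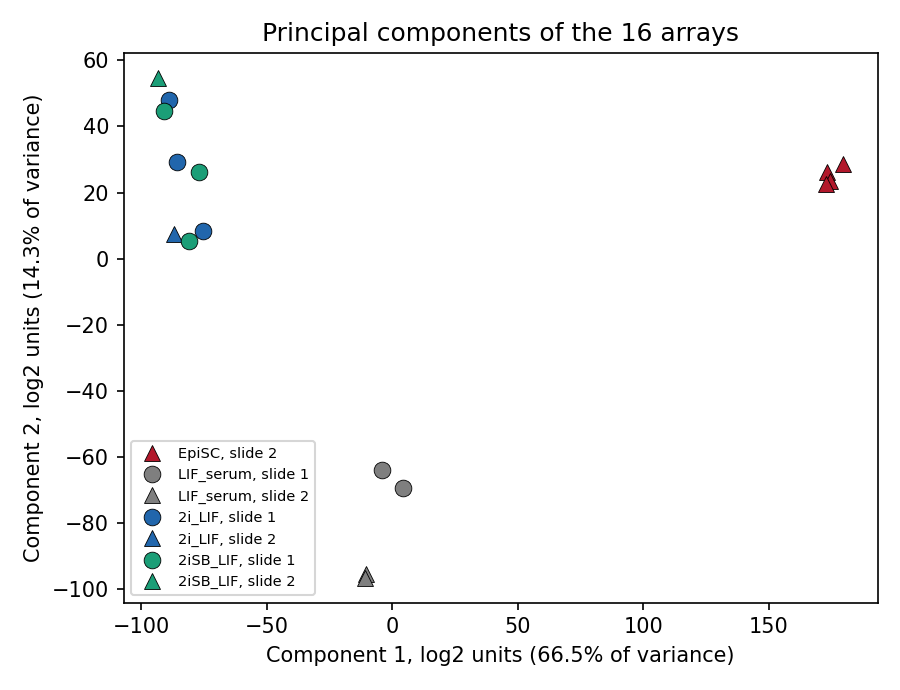
First against second principal component of the tested genes with no missing value on any array, in units of component score. There is 1 point per array, coloured by group, circles for slide 1 and triangles for slide 2. The 4 EpiSC arrays lie at scores from 173 to 180 on the first component, which holds 66.5% of the variance, and every other array lies at 4.19 or lower.

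The first comparison asks how primed EpiSC lines differ from naive LIF_serum lines. Differences are given on the log2 scale with the standard error (SE) of the limma fit, n = 4 arrays per group. Each array is a different line, and p-values rest on the spread between arrays within groups, joined over all 4 groups. That spread also holds differences of slide, and of the codes LS and LSFF within LIF_serum. Among the 10 largest falls of genes measured in both groups, Dppa5a, Esrrb and Zfp42 belong to the naive pluripotency list. Dppa5a, an RNA-binding protein of early embryo cells, had a log2 difference of −11.54 (SE 0.16, adjusted p = 5.2e-16). Esrrb, an orphan nuclear receptor of the naive network, was at −8.47 (SE 0.19, adjusted p = 1.1e-13), and Zfp42 (Rex1), a widely used naive marker, at −8.22 (SE 0.33, adjusted p = 9.6e-11). Dnmt3l, the cofactor of the de novo DNA methyltransferases, was at −8.50 (SE 0.16), and Tdh, the threonine dehydrogenase on which mouse embryonic stem cells depend, at −7.73 (SE 0.37). Pigp, Fam25c, Tuba3a, Mageb16 and Gtsf1l lay between −11.44 and −7.60. Rpl10l, Fthl17-ps1 and Zscan4f were not well above background on any EpiSC array. With the background floor used here, their signal was at least 2280-fold (adjusted p = 7.6e-14), 1296-fold (adjusted p = 3.3e-07) and 1222-fold (adjusted p = 6.5e-08) lower there.

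In EpiSC Ccl2, a chemokine, rose by 6.95 (SE 0.79, adjusted p = 4.5e-06), and Fgf5, a growth factor of the post-implantation epiblast, by 5.41 (SE 0.90, adjusted p = 0.00014). Dusp2, a phosphatase of ERK, rose by 5.36 (SE 0.39, adjusted p = 4.1e-08), and Igfbp5, an insulin-like growth factor binding protein, by 5.54 (SE 0.44). Heph, Egr4, Akr1c18, Calcr, Asb4 and Sprr1a rose by 5.16 to 5.56. Cer1, a secreted antagonist of Nodal and BMP, was at least 98.9-fold higher (adjusted p = 4.7e-10), Mmp10 at least 27.6-fold (adjusted p = 2.1e-07) and Crispld1 at least 25.9-fold (adjusted p = 3.4e-06). For each of these 26 genes every EpiSC array lay on the same side of every LIF_serum array, which was a condition for naming it.

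Of 15506 genes, 5207 were called between EpiSC and LIF_serum, 2780 higher and 2427 lower in EpiSC. Over all genes tested the arrays of the groups did not overlap for 58.8% (2.86% by chance). With the slide as a block 5229 were called, and within slide 2 alone 5703. Centring arrays on the median shifted the median difference of all genes from 0.07 to 0.61 and the share of higher calls from 53.4% to 75.9%, so small differences depend on the scaling.

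Among the fixed lists, 16 of 20 naive pluripotency genes fell and none rose (median log2 difference −4.59, camera adjusted p = 1.3e-12, and adjusted p = 0.043 with an estimated correlation). The median was −4.76 with the slide as a block and −4.60 within slide 2. All 16 measured germline genes fell (median −5.34, or −4.47 with bounded genes at their bound, camera adjusted p = 3.7e-12, and adjusted p = 0.043 with an estimated correlation), and 13 fell with normexp background correction (median −2.76). Sycp3, of the meiotic chromosome axis, had a difference of −9.62 (SE 0.31, adjusted p = 1.1e-11), with 2 of 4 EpiSC arrays well above background, or at least 670-fold lower, and Ddx4, the germ cell RNA helicase, was at least 189-fold lower (adjusted p = 4.7e-11). Of 10 genes of 2-cell-like cells, 7 fell (median −7.12, or −5.33 at their bounds and −3.10 with normexp, camera adjusted p = 8.4e-05, and adjusted p = 0.31 with an estimated correlation). Among 15 core pluripotency genes 5 fell (median −0.44, turning to 0.10 with median centring, camera adjusted p = 0.015, and adjusted p = 0.43 with an estimated correlation). Sox2 had a difference of −1.48 (SE 0.16, adjusted p = 2.4e-06), while Pou5f1, which encodes Oct4, was at −0.44 (SE 0.16, adjusted p = 0.035), under the 2-fold minimum.

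Primed epiblast genes rose in 9 of 14 cases and fell in none (median 1.65, camera adjusted p = 0.013, and adjusted p = 0.38 with an estimated correlation). They included Pou3f1 (Oct6), at 2.66 (SE 0.27, adjusted p = 1.3e-06), and Dnmt3a, a de novo DNA methyltransferase, at 1.46 (SE 0.25, adjusted p = 0.00019). Of 16 ERK feedback genes 8 rose and 1 fell (median 2.06, camera adjusted p = 0.020, and adjusted p = 0.43 with an estimated correlation). Fosl1, a subunit of AP-1, rose by 4.65 (SE 0.60, adjusted p = 1.6e-05), with 2 of 4 LIF_serum arrays well above background, and Dusp6, a feedback phosphatase, by 3.50 (SE 0.39, adjusted p = 4e-06), whereas Etv5, an ETS factor downstream of FGF, was at −1.04 (SE 0.20, adjusted p = 0.00051), a call lost without LIF_serum array 1 or 2. Among 17 Hox genes 12 rose and 1 fell (median 1.64, or 1.25 at their bounds, camera adjusted p = 0.0096, and adjusted p = 0.43 with an estimated correlation), while with normexp background correction 7 rose, 0 fell and the median was 0.73. LIF/STAT3 targets fell in 6 of 13 cases and rose in 1 (median −0.54, and 0.00 with median centring; camera adjusted p = 0.012, and adjusted p = 0.25 with an estimated correlation). The receptor gene Lifr was at −2.52 (SE 0.28, adjusted p = 3.2e-06), while Junb, also a target of ERK, rose by 3.14 (SE 0.23, adjusted p = 5.7e-08).

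The epithelial and fibroblast lists were both called. Of 12 epithelial genes 6 fell (median −1.45, and −0.91 with median centring, camera adjusted p = 0.013, and adjusted p = 0.43 with an estimated correlation), among them Cdh1 (E-cadherin), at −2.56 (SE 0.40, adjusted p = 7.9e-05). Of 10 mesenchymal genes 5 rose (camera adjusted p = 0.15), among them Zeb2, a repressor of Cdh1, at 3.94 (SE 0.79, adjusted p = 0.00069). Fibroblast (feeder cell) markers rose in 19 of 20 cases (median 3.49, camera adjusted p = 3.4e-05, and adjusted p = 0.43 with an estimated correlation). Their median difference was 4.26 with the slide as a block and 5.04 within slide 2. It was 1.52 against LIF_serum arrays 1 and 2 alone. The epithelial median was −2.09 with the slide as a block and −2.41 within slide 2. Against LIF_serum arrays 1 and 2 alone, the camera calls of the epithelial, ERK feedback, Hox, glycolysis and oxidative phosphorylation lists were lost, and against arrays 3 and 4 alone those of cholesterol synthesis and core pluripotency.

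Cholesterol synthesis genes rose in 5 of 19 cases (median 0.78, camera adjusted p = 0.019, and adjusted p = 0.43 with an estimated correlation), a camera call lost with the slide as a block and without LIF_serum array 2. With median centring 12 of the 19 rose (median 1.31). Oxidative phosphorylation fell in 2 of 27 genes (median −0.30, turning to 0.24 with median centring, camera adjusted p = 0.015, and adjusted p = 0.58 with an estimated correlation). Glycolysis fell in 3 of 21 genes (median −0.25, turning to 0.28 with median centring, camera adjusted p = 0.045, and adjusted p = 0.54 with an estimated correlation), a call lost without LIF_serum array 3 or 4 or EpiSC array 1 or 3. Camera called none of the other lists. Among them, 6 of 14 Nodal/Activin targets rose and none fell (adjusted p = 0.099), with Lefty2, the feedback inhibitor of Nodal, at 4.20 (SE 0.55, adjusted p = 1.8e-05). Of 16 primitive streak and mesendoderm genes 9 rose and 4 fell (adjusted p = 0.45), and of 13 neural genes 6 rose and 1 fell (adjusted p = 0.14). Higher and lower members were 4 and 2 of 20 imprinted genes (adjusted p = 0.32), 4 and 2 of 15 Wnt/beta-catenin targets (adjusted p = 0.71), 3 and 3 of 12 primitive endoderm genes (adjusted p = 0.96) and 1 and 3 of 12 trophectoderm genes (adjusted p = 0.16). They were 1 and 3 of 9 BMP targets (adjusted p = 0.16), 1 and 3 of 9 DNA methylation enzymes (adjusted p = 0.20), 0 and 1 of 17 Myc and ribosome biogenesis genes (adjusted p = 0.35) and 2 and 1 of 14 cell cycle inhibitors and p53 targets (adjusted p = 0.45). Counts adjusted over the list alone were the same except in primitive endoderm, where 4 rose. Median, mean and test differed in sign for primitive endoderm (median 0.38, mean −0.34) and for Myc and ribosome biogenesis (median −0.08, mean 0.02).

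**Figure D2:**
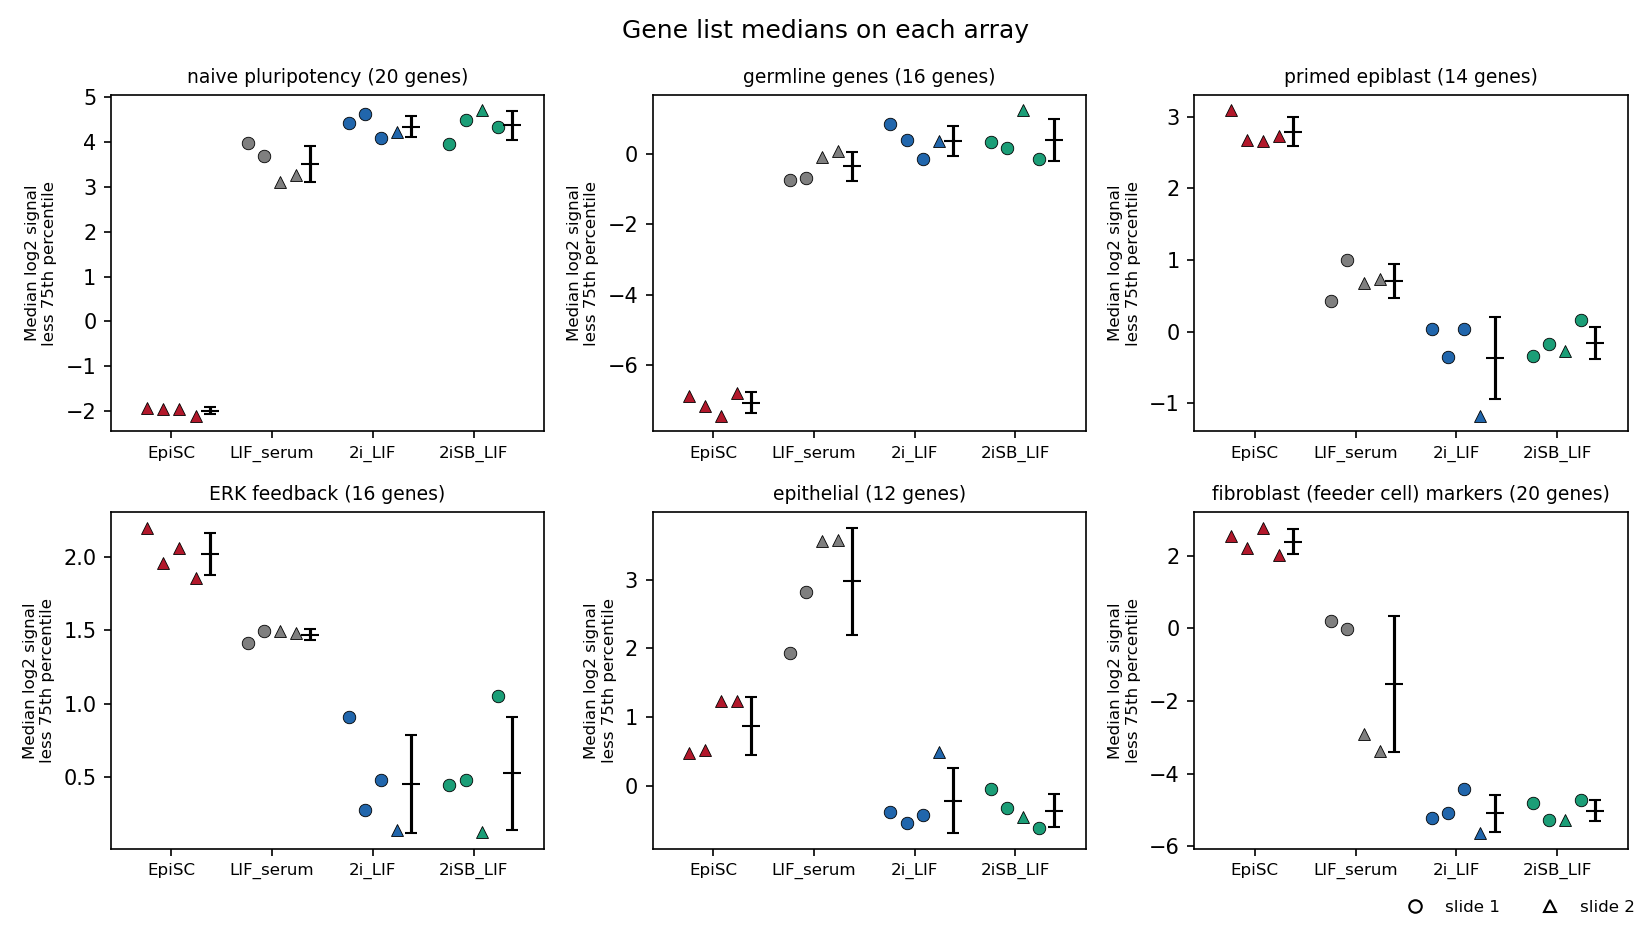
Median log2 signal over the members of 6 fixed lists on each array, relative to the array's 75th percentile, with 1 point per array and the group mean ± SD (n = 4) beside the points. The naive list lies between 3.11 and 4.71 on all arrays but those of EpiSC, where it lies between −2.11 and −1.92, and the fibroblast list runs from −5.64 in 2i_LIF to 2.78 in EpiSC.

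The next comparisons ask how each ground-state medium differs from serum with LIF. In 2i_LIF Plac8 was at −7.48 (SE 0.38, adjusted p = 1.9e-08), Acta2, smooth muscle actin, at −7.37 (SE 0.53, adjusted p = 4.4e-07), and Tagln, an actin-binding protein of contractile cells, at −5.51 (SE 0.28, adjusted p = 1.9e-08). The keratin genes Krt8 and Krt19, of simple epithelia, were at −5.71 (SE 0.71) and −5.05 (SE 0.73), and Esrp1, an epithelial splicing factor, at −5.03 (SE 0.33). Myl9, Kif1a, Spink1 and Col1a1 lay between −5.58 and −5.22. Thbs1, which encodes thrombospondin, was at least 259-fold lower (adjusted p = 3.3e-08), and Psmb8, of the immunoproteasome, at least 112-fold (adjusted p = 9.8e-06). The Y-linked Eif2s3y was at least 131-fold lower (adjusted p = 0.0024) with an SD of 4.07 among LIF_serum arrays, of which array 2 was far below the others.

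Rises in 2i_LIF were smaller. Gsc, the homeobox gene goosecoid, rose by 3.81 (SE 0.51, adjusted p = 9.3e-05), Mal, a proteolipid of membrane rafts, by 3.75 (SE 0.55), Kiss1, the kisspeptin precursor, by 3.65 (SE 0.69), and Ppp1r14d, a phosphatase inhibitor, by 3.39 (SE 0.31, adjusted p = 3e-06). St8sia6, DXBay18, Iqca, Rhox3h, Dido1 and Xlr5a rose by 3.33 to 3.47, and the adjusted p of Rhox3h was 0.036 (SE 1.15), a call lost without any single LIF_serum array. Sash3 was at least 22.2-fold higher (adjusted p = 5.2e-06), Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, at least 13.4-fold (adjusted p = 0.00088), and Asb2 at least 5.68-fold (adjusted p = 0.00068). Between 2i_LIF and LIF_serum 2837 genes were called, 968 higher and 1869 lower, and 27.2% of all genes tested did not overlap (2.86% by chance). With the slide as a block 2898 were called, within slide 1 1682, and within slide 2, where 2i_LIF has 1 array, 4204.

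In 2iSB_LIF against LIF_serum, Gsc rose by 4.16 (SE 0.51, adjusted p = 4e-05), Sox21, a SoxB2 factor, by 3.72 (SE 0.46, adjusted p = 4.4e-05), and Lrrc15 by 3.57 (SE 0.40, adjusted p = 1.7e-05). Rhox3h, Rhox3f, Rhox3a and Slx, of X-linked gene families, together with Akr1c13, Nlrp4c and Iqca, rose by 3.44 to 3.92. Rhox3h, Rhox3f, Rhox3a and Slx had SEs of 1.13 to 1.17, and their calls were lost without 2iSB_LIF array 2 or without array 3. Col1a1 was at −6.14 (SE 0.62, adjusted p = 7.5e-06), Myl9, a myosin light chain, at −5.91 (SE 0.43, adjusted p = 4.2e-07), and Tagln at −5.60 (SE 0.28, adjusted p = 1.3e-08). Spink1, Krt8, Zscan4f, Zscan4a, Kif1a, Krt19 and Krt18 lay between −6.06 and −5.09. Thbs1 was at least 281-fold lower (adjusted p = 9.8e-08), Gbp2, an interferon-induced GTPase, at least 271-fold (adjusted p = 4.7e-07) and Eif2s3y at least 176-fold (adjusted p = 0.0017), a value for the LIF_serum mean that does not hold for array 2, at −4.26 against 3.61 to 4.12 on the other arrays. Cyp1a1 was at least 18.6-fold higher (adjusted p = 0.00039), Dcaf8l at least 18.0-fold (adjusted p = 0.0038) and Ffar2, a receptor for short-chain fatty acids, at least 8.97-fold (adjusted p = 0.00011). In this comparison 3115 genes were called, 1056 higher and 2059 lower, and 29.6% of all genes tested did not overlap (2.86% by chance). With the slide as a block 3179 were called, within slide 1 1756, and within slide 2, where 2iSB_LIF has 1 array, 4964. With passage number as a covariate 1899 were called, though passage also differed in part between these groups.

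Fibroblast markers fell in 16 of 20 cases in 2i_LIF (median −3.83, or −3.58 at their bounds and −2.18 with normexp, camera adjusted p = 1.4e-11, and adjusted p = 0.23 with an estimated correlation). In 2iSB_LIF 17 of 20 fell (median −3.96, or −2.34 with normexp, camera adjusted p = 2.3e-11, and adjusted p = 0.25 with an estimated correlation). Their medians were −4.25 and −4.51 with the slide as a block, −5.66 and −5.97 within slide 1, and −2.37 and −2.21 within slide 2. Epithelial genes fell in 10 of 12 cases in 2i_LIF and 11 in 2iSB_LIF (medians −2.73 and −3.06, camera adjusted p = 5.1e-07 and 8.8e-07, and adjusted p = 0.29 and 0.25 with an estimated correlation). The epithelial medians were −2.28 and −2.35 within slide 1, and −2.69 and −3.80 within slide 2, where fibroblast markers differed least. Epcam was at −2.66 (SE 0.33, adjusted p = 5.2e-05) and −2.91 (SE 0.33, adjusted p = 2e-05), while Cdh1 was at −0.20 (SE 0.40) and −0.52 (SE 0.40) and was not called. Primitive endoderm genes fell in 6 and 7 of 12 cases (medians −2.31 and −1.72, the former −1.34 with normexp, camera adjusted p = 9.2e-05 and 0.00018, and adjusted p = 0.29 and 0.27 with an estimated correlation). They included the basement membrane genes Lamb1, at −2.81 (SE 0.34) and −3.30 (SE 0.34), and Col4a1, at −2.63 (SE 0.58) and −3.13 (SE 0.58), which fibroblasts also express. The primitive endoderm medians were −0.90 and −1.25 within slide 1 and −3.30 and −2.92 within slide 2.

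Naive pluripotency genes rose in 6 of 20 cases in 2i_LIF and in 4 in 2iSB_LIF, and none fell (medians 0.62 and 0.57, camera adjusted p = 0.011 and 0.012, and adjusted p = 0.42 and 0.44 with an estimated correlation). Their medians were 0.20 and 0.10 within slide 1 and 1.04 and 1.46 within slide 2, and against LIF_serum arrays 1 and 2 alone both camera calls were lost. Prdm14, a repressor of FGF signalling and DNA methylation genes, rose by 2.46 (SE 0.33, adjusted p = 9.2e-05) and 2.36 (SE 0.33, adjusted p = 0.00011), and Tbx3 by 1.73 (SE 0.30, adjusted p = 0.00062) and 1.54 (SE 0.30, adjusted p = 0.0013). Dnmt3l was at −3.30 (SE 0.16, adjusted p = 1.9e-08) and −3.28 (SE 0.16, adjusted p = 1.3e-08), and Dnmt3b, a de novo DNA methyltransferase, at −3.04 (SE 0.40, adjusted p = 8.3e-05) and −2.17 (SE 0.40, adjusted p = 0.00094). These were the only 2 of 9 DNA methylation enzymes that passed in either medium (camera adjusted p = 0.22 and 0.40). Of 14 primed epiblast genes 7 fell in each medium (medians −1.33 and −1.28, camera adjusted p = 0.00094 and 0.0019, and adjusted p = 0.23 and 0.25 with an estimated correlation). Pou3f1 was at −3.25 (SE 0.27, adjusted p = 1.4e-06) and −3.68 (SE 0.27, adjusted p = 4e-07).

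ERK feedback genes fell in 4 and 5 of 16 cases (medians −0.75 and −0.74, the former −0.50 with normexp, camera adjusted p = 0.049 and 0.043, and adjusted p = 0.48 and 0.44 with an estimated correlation). Without LIF_serum array 1 or without array 2 both camera calls were lost, as was that of 2i_LIF without its array 3 or 4 and that of 2iSB_LIF without its array 1 or 3. Against LIF_serum arrays 3 and 4 alone the ERK feedback medians were 0.24 and −0.05. Within slide 1 they were −1.05 and −1.33, and within slide 2 −0.38 and −0.54. Dusp4, an ERK phosphatase, was at −2.77 (SE 0.44, adjusted p = 0.00035) and −2.40 (SE 0.44, adjusted p = 0.00091). Genes of 2-cell-like cells fell in 7 of 10 cases in each medium (medians −3.35 and −3.54, or −2.06 and −2.20 with normexp, camera adjusted p = 0.0016 and 0.00081, and adjusted p = 0.35 and 0.27 with an estimated correlation). Imprinted genes fell in 12 and 11 of 20 cases and 1 rose in each medium (medians −1.33 and −1.40, camera adjusted p = 0.0038 and 0.0067, and adjusted p = 0.23 and 0.25 with an estimated correlation). Nnat, which encodes neuronatin, was at −4.32 (SE 0.39, adjusted p = 2.9e-06) and −4.99 (SE 0.39, adjusted p = 7.1e-07). Cholesterol synthesis genes rose in 3 and 5 of 19 cases (medians 0.61 and 0.66, camera adjusted p = 3.6e-05 and 1.4e-05, and adjusted p = 0.29 and 0.25 with an estimated correlation), with Cyp51, lanosterol demethylase, at 1.66 (SE 0.16, adjusted p = 4.2e-06) and 1.63 (SE 0.16, adjusted p = 4.2e-06). The cholesterol synthesis medians were 0.85 and 0.99 within slide 1 and 0.57 and 0.25 within slide 2. Glycolysis fell in 2 and 3 of 21 genes (medians −0.31 and −0.35, camera adjusted p = 0.011 and 0.017, and adjusted p = 0.49 and 0.52 with an estimated correlation). Both glycolysis calls were lost with quantile normalization, and that of 2i_LIF also without its array 2. Nodal/Activin targets fell in 8 of 14 cases in 2iSB_LIF (median −1.26, camera adjusted p = 0.00047, and adjusted p = 0.25 with an estimated correlation). In 2i_LIF 3 rose and 3 fell (adjusted p = 0.53).

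Arrays did not overlap for any called gene named against LIF_serum, apart from Myc in 2i_LIF. For the genes named as largest changes this was a condition of being named. Each list called against LIF_serum kept the sign of its median with the slide as a block and within each slide. Camera called none of the other lists. In 2i_LIF and 2iSB_LIF respectively, higher and lower members were 1 and 2, and 1 and 2, of 15 core pluripotency genes (adjusted p = 0.99 and 0.83). They were 2 and 8, and 3 and 7, of 16 primitive streak and mesendoderm genes (adjusted p = 0.10 and 0.064), 0 and 3, and 1 and 2, of 13 neural genes (adjusted p = 0.71 and 0.84), and 3 and 5, and 4 and 5, of 12 trophectoderm genes (adjusted p = 0.22 and 0.52). Of 15 Wnt/beta-catenin targets 1 rose in each medium and 4 and 6 fell (adjusted p = 0.19 and 0.12), and of 9 BMP targets 1 and 0 rose and 4 and 2 fell (adjusted p = 0.074 and 0.14), including the BMP target Id1, at −4.07 (SE 0.54, adjusted p = 8.6e-05) and −3.36 (SE 0.54, adjusted p = 0.00035). LIF/STAT3 targets rose in 3 of 13 cases in each and fell in 1 and 2 (adjusted p = 0.54 and 0.87). Germline genes rose in 3 and 4 of 16 cases and fell in 3 in each (adjusted p = 0.53 and 0.74), and Dazl, an RNA-binding protein of germ cells, rose by 3.04 (SE 0.48, adjusted p = 0.00035) and 2.64 (SE 0.48, adjusted p = 0.00088). No gene of 27 in oxidative phosphorylation was called (adjusted p = 0.13 and 0.47). Of 17 Myc and ribosome biogenesis genes only Myc itself fell (adjusted p = 0.91 and 0.98), and its 2i_LIF call was lost without LIF_serum array 1 or 2 or 2i_LIF array 1 or 4. Of 14 cell cycle inhibitors and p53 targets 1 rose, Cdkn2a, and 1 fell (adjusted p = 0.37 and 0.37). Of 17 Hox genes 4 and 3 rose and 2 and 3 fell (adjusted p = 0.77 and 0.74), and of 10 mesenchymal genes 1 rose and 3 fell in each (adjusted p = 0.19 and 0.15).

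Counts against LIF_serum adjusted over the list alone differed from these in a few lists. In 2i_LIF they were 8 primed epiblast, 11 epithelial, 18 fibroblast, 6 trophectoderm, 5 BMP, 4 Nodal/Activin, 4 mesenchymal, 3 Hox, 2 neural and 0 Myc genes lower, and 3 streak genes higher. In 2iSB_LIF they were 7 ERK feedback, 20 fibroblast, 6 trophectoderm, 4 mesenchymal and 0 Myc genes lower, and 5 trophectoderm and 2 imprinted genes higher. Median, mean and test differed in sign in both media for core pluripotency, neural and Hox genes, and in 2i_LIF also for LIF/STAT3 targets, DNA methylation enzymes and Myc genes, none of them called.

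The comparison of 2iSB_LIF with 2i_LIF asks what blocking Activin, Nodal and TGF-beta receptors adds. Targets of that pathway were lower. Lefty1, a feedback inhibitor of Nodal, was at −8.88 (SE 0.49, adjusted p = 2.9e-07), with 1 of 4 2iSB_LIF arrays well above background, so that the size of the fall is uncertain. Lefty2, its neighbour with the same role, was at −6.13 (SE 0.55, adjusted p = 0.00013). Duxbl2 was at −2.60 (SE 0.29, adjusted p = 0.0012), Steap2, a metalloreductase, at −2.38 (SE 0.35, adjusted p = 0.015), Fhod3, a formin, at −2.25 (SE 0.32, adjusted p = 0.013), and Igfbpl1 at −2.16 (SE 0.34, adjusted p = 0.025). Duxbl1 was at least 4.11-fold lower (adjusted p = 0.001) and Arnt2 at least 2.06-fold (adjusted p = 0.024). Gsn, which encodes the actin-severing protein gelsolin, rose by 1.81 (SE 0.28, adjusted p = 0.024) and Cotl1, another actin-binding protein, by 1.19 (SE 0.20, adjusted p = 0.044). For each of these genes every 2iSB_LIF array lay on the same side of every 2i_LIF array. This was a condition for naming them, apart from Lefty1, which was named as a list member. The p-values of these genes rest on the spread joined over all groups, EpiSC included.

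In all, 13 genes were called between 2iSB_LIF and 2i_LIF, 2 higher and 11 lower, and 868 had an unadjusted p under 0.05, where chance gives 775. Of all genes tested 2.16% did not overlap, below the 2.86% that chance gives. With the slide as a block 17 were called, 2 within slide 1, and 2232 within slide 2, where each group has 1 array whose spread is taken from the other groups. With only the 2iSB_LIF and 2i_LIF arrays in the fit 3 were called, so most of the 13 calls depend on the fit over all groups. The mean correlation within EpiSC was 0.993, higher than within 2i_LIF (0.971) and 2iSB_LIF (0.974). Without 2iSB_LIF array 1 the count was 27, and the calls of Gsn, Cotl1, Igfbpl1 and Arnt2 were each lost without at least 1 single array. Nodal/Activin targets were lower as a list, with 3 of 14 called over all genes and 5 when adjusted over the list alone (median −0.73, mean −1.81, camera adjusted p = 2.9e-12, and adjusted p = 0.023 with an estimated correlation). The list's median was also −0.73 with the slide as a block, −0.63 within slide 1 and −0.96 within slide 2. The further members lower over the list alone were Pmepa1, at −2.02 (SE 0.71), and Smad7, at −1.60 (SE 0.38), both feedback inhibitors of SMAD signalling. Nodal itself was at −0.56 (SE 0.26, adjusted p = 0.90) and Tdgf1, its coreceptor, at −0.49 (SE 0.15, adjusted p = 0.46). Camera called none of the other 24 lists (adjusted p from 0.67 to 1.00), with no member called over all genes. Adjusted over the list alone, 1 BMP target, Bmp4 (log2 difference 1.51, SE 0.46), and 1 imprinted gene, Phlda2 (2.57, SE 0.52), were higher. Fibroblast markers were at a median of −0.12. Median, mean and test differed in sign for naive pluripotency, primed epiblast, neural, glycolysis and imprinted genes.

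**Figure D3:**
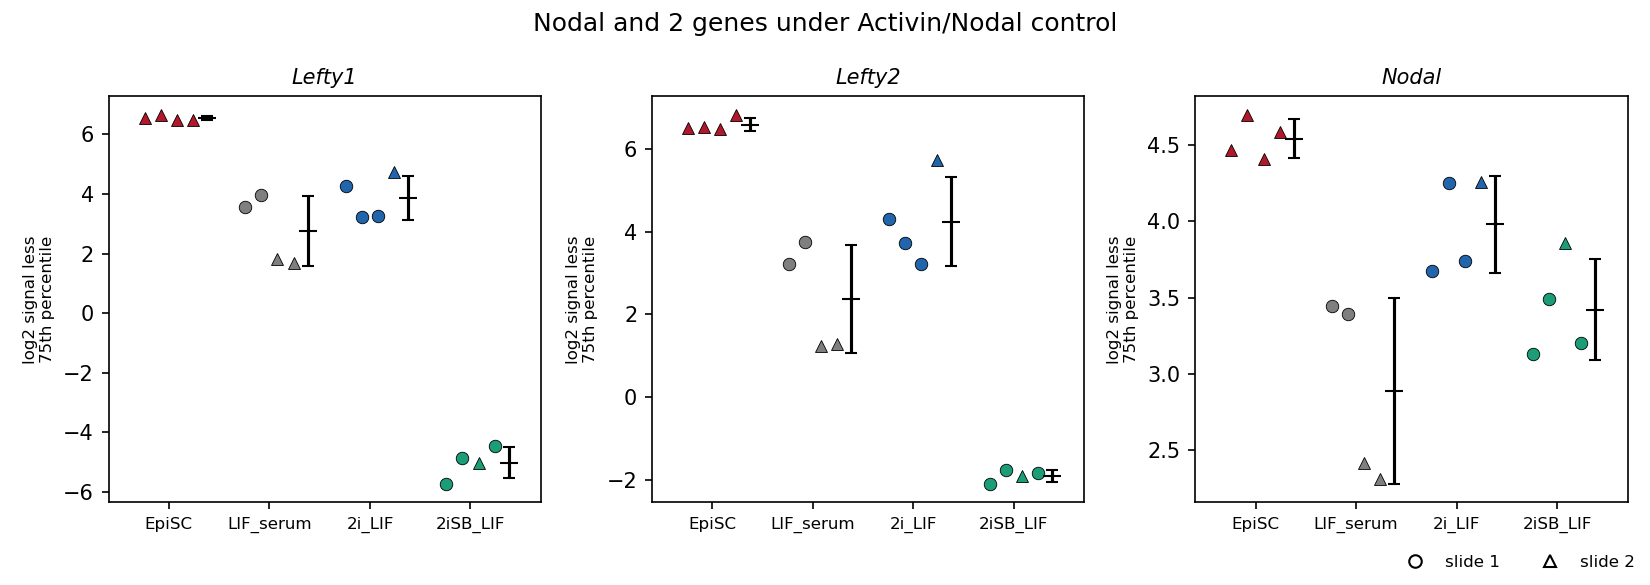
Log2 signal of Lefty1, Lefty2 and Nodal on each array, relative to the array's 75th percentile, with 1 point per array and the group mean ± SD (n = 4) beside the points. Lefty1 and Lefty2 are lower on all 4 2iSB_LIF arrays than on all 4 2i_LIF arrays, while the Nodal difference of −0.56 (SE 0.26) was not called.

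The last comparisons set each ground-state group against primed EpiSC. In 2i_LIF Dppa5a was higher by 11.29 (SE 0.16, adjusted p = 7.1e-16) and in 2iSB_LIF by 11.11 (SE 0.16, adjusted p = 8.9e-16). Pigp, of glycosylphosphatidylinositol anchor synthesis, Tuba3a and Tuba3b, alpha-tubulins, and Rhox2h, an X-linked homeobox gene, were higher by 9.39 to 11.28 in 2i_LIF and by 9.67 to 10.85 in 2iSB_LIF. Rpl10l was at least 5836-fold higher in 2i_LIF (adjusted p = 3e-14) and 5004-fold in 2iSB_LIF, and Fthl17-ps1 at least 3954-fold (adjusted p = 4.4e-08) and 6308-fold. Among the genes lower in 2i_LIF, Acta2 was at −9.22 (SE 0.53, adjusted p = 2.1e-09), Dusp2 at −8.00 (SE 0.39, adjusted p = 3.4e-10), Col1a1 at −7.53 (SE 0.62, adjusted p = 9.9e-08), and Pkdcc and Lor at −8.38 and −8.03. In 2iSB_LIF Lefty2 was at −8.48 (SE 0.55, adjusted p = 7.9e-09), Wt1, the Wilms tumour transcription factor, at −8.16 (SE 0.41, adjusted p = 5e-10), Fosb, of the AP-1 complex, at −7.53 (SE 0.53, adjusted p = 1.9e-08), and Col1a1 and Pkdcc at −8.45 and −7.59. Thbs1 was at least 1247-fold (adjusted p = 1.4e-10) and 1349-fold (adjusted p = 3.4e-10) lower, Prss23 at least 738-fold in 2i_LIF (adjusted p = 1.1e-12) and Actc1, cardiac actin, at least 1625-fold in 2iSB_LIF (adjusted p = 6e-09).

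Against EpiSC 5796 genes were called in 2i_LIF, 2612 higher and 3184 lower, and 5631 in 2iSB_LIF, 2513 higher and 3118 lower, and 55.2% and 54.2% of all genes tested did not overlap (2.86% by chance). With the slide as a block 5547 and 5511 were called, and within slide 2, where each ground-state group has 1 array, 6155 and 5998. Median centring shifted the median of all genes from −0.04 in both to −0.58 and −0.56, and the share of higher calls from 45.1% to 25.1% and from 44.6% to 25.5%.

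Naive pluripotency genes rose in 17 of 20 cases in each ground-state group (medians 4.77 and 4.67, camera adjusted p = 3.6e-12 and 1.5e-12, and adjusted p = 0.048 and 0.044 with an estimated correlation). All 16 germline genes rose (medians 6.71 and 6.79, or 4.96 and 5.02 at their bounds and 3.08 and 3.45 with normexp, camera adjusted p = 2.4e-11 and 3e-11, and adjusted p = 0.048 and 0.044 with an estimated correlation). Genes of 2-cell-like cells rose in 7 of 10 cases (medians 3.77 and 3.35, or 2.92 and 2.73 at their bounds, camera adjusted p = 0.0078 and 0.012, and adjusted p = 0.42 and 0.44 with an estimated correlation), calls lost with normexp, whose medians were 0.95 and 0.87 with 5 and 3 genes higher. Of 15 core pluripotency genes 6 rose and 1 fell (medians 0.27 and 0.51, turning to −0.27 and −0.01 with median centring, camera adjusted p = 0.044 and 0.029, and adjusted p = 0.55 and 0.51 with an estimated correlation), calls lost with the slide as a block, and in 2i_LIF also without its array 2 or 3. Nanog rose by 2.29 (SE 0.24, adjusted p = 1.2e-06) and 2.14 (SE 0.24, adjusted p = 2.3e-06), and the gene that fell, Lin28a, an RNA-binding inhibitor of let-7, was at −2.84 (SE 0.23, adjusted p = 6.5e-08) and −2.48 (SE 0.23, adjusted p = 2.7e-07). LIF/STAT3 targets rose in 4 and fell in 2 of 13 cases (medians 0.80 and 0.67, or 0.26 and 0.15 with median centring, camera adjusted p = 0.016 and 0.037, and adjusted p = 0.18 and 0.26 with an estimated correlation), and the 2iSB_LIF call was lost with the slide as a block. Oxidative phosphorylation rose in 3 and 2 of 27 genes (medians 0.44 and 0.36, turning to −0.10 and −0.16 with median centring, camera adjusted p = 0.0023 and 0.0081, and adjusted p = 0.55 and 0.61 with an estimated correlation).

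Primed epiblast genes fell in 10 of 14 cases in each ground-state group (medians −2.80 and −2.57, camera adjusted p = 0.00027 and 0.00037, and adjusted p = 0.15 and 0.16 with an estimated correlation). Fgf5 was at −8.94 (SE 0.90, adjusted p = 7.5e-07) and −9.59 (SE 0.90, adjusted p = 3.5e-07), with 2 and 1 of 4 ground-state arrays well above background, or at least 323-fold and 435-fold lower. Of 16 ERK feedback genes 11 and 10 fell and 1, Etv5, rose (medians −2.41 and −2.02, camera adjusted p = 0.0026 and 0.0025, and adjusted p = 0.32 and 0.27 with an estimated correlation). Nodal/Activin targets fell in 8 and 10 of 14 cases (medians −1.49 and −1.63, camera adjusted p = 0.044 and 0.0016, and adjusted p = 0.46 and 0.24 with an estimated correlation), and the 2i_LIF call was lost without EpiSC array 1 and without 2i_LIF array 2 or 3. Imprinted genes fell in 12 and 10 of 20 cases and rose in 1 and 0 (medians −1.67 and −1.46, camera adjusted p = 0.0078 and 0.0096, and adjusted p = 0.16 and 0.17 with an estimated correlation). Mesenchymal genes fell in 7 of 10 cases (medians −2.02 and −2.06, camera adjusted p = 0.034 and 0.021, and adjusted p = 0.32 and 0.26 with an estimated correlation). Fibroblast markers moved in the same direction as these lists and fell in all 20 cases (medians −8.00 and −8.47, or −7.16 and −7.18 at their bounds and −5.13 and −5.11 with normexp, camera adjusted p = 1e-10 and 4.2e-11, and adjusted p = 0.16 and 0.17 with an estimated correlation). Their medians were −9.21 and −9.34 with the slide as a block and −8.26 and −7.91 within slide 2. Each list called against EpiSC kept the sign of its median with the slide as a block and within slide 2.

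Camera called none of the other lists against EpiSC. In 2i_LIF and 2iSB_LIF respectively, 3 streak genes of 16 rose and 8 fell in each (adjusted p = 0.15 and 0.16), 1 primitive endoderm gene of 12 rose and 7 and 6 fell (adjusted p = 0.062 and 0.068), 2 and 3 of 13 neural genes rose and 6 fell (adjusted p = 0.15 and 0.22), and 3 and 5 of 12 trophectoderm genes rose and 6 and 5 fell (adjusted p = 0.99 and 0.86). Wnt/beta-catenin targets rose in 3 of 15 cases and fell in 6 and 5 (adjusted p = 0.63 and 0.55), BMP targets rose in 2 and 3 of 9 and fell in 4 and 3 (adjusted p = 0.90 and 1.00), and DNA methylation enzymes rose in 3 of 9 and fell in 2 (adjusted p = 0.47 and 0.39). Dnmt3a and Dnmt3b fell, and Tet1, which oxidises methylcytosine, rose by 2.56 (SE 0.32, adjusted p = 6.6e-06) and 2.51 (SE 0.32, adjusted p = 7.8e-06). Of 21 glycolysis genes 2 rose and 3 fell (adjusted p = 0.99 and 0.98), of 19 cholesterol synthesis genes 1 rose and 1 and 0 fell (adjusted p = 0.94 and 0.78), and of 17 Myc and ribosome biogenesis genes 2 and 0 rose and 1 fell (adjusted p = 0.42 and 0.47). Of 14 cell cycle inhibitors and p53 targets 2 and 1 rose and 1 and 2 fell (adjusted p = 1.00 and 0.98), of 17 Hox genes 3 and 2 rose and 10 and 7 fell (adjusted p = 0.092 and 0.074), and of 12 epithelial genes 2 and 3 rose and 6 fell (adjusted p = 0.27 and 0.26). Counts adjusted over the list alone were the same except for 7 neural genes lower in 2i_LIF, and 4 BMP targets, 8 Hox and 8 mesenchymal genes lower and 3 Hox genes higher in 2iSB_LIF. Median, mean and test differed in sign for Myc and ribosome biogenesis in both groups, and in 2iSB_LIF also for trophectoderm, BMP targets and cell cycle inhibitors.

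The list of sex chromosome genes was read array by array. Eif2s3y, a Y-linked translation factor gene, was well above background on all LIF_serum and EpiSC arrays and on none of the 8 ground-state arrays. Its log2 signals were 3.09 to 4.12 on LIF_serum arrays 1, 3 and 4 and EpiSC arrays 1 and 2, but −4.26 on LIF_serum array 2 and −2.28 and −3.55 on EpiSC arrays 3 and 4. Ddx3y, a Y-linked RNA helicase gene, gave the same pattern. Uty was well above background on LIF_serum arrays 1, 3 and 4 and EpiSC arrays 1 and 2, and its spot on 2iSB_LIF array 1 was an outlier and left out. Xist, the RNA that silences an X chromosome in female cells, was highest on EpiSC arrays 3 and 4, at −1.04 and −0.83. The median signal of 619 X-linked genes less that of autosomal genes lay between −0.31 and −0.06 on LIF_serum and EpiSC arrays. On the ground-state arrays it was 0.61, 0.36, −0.44 and −0.35 in 2i_LIF and −0.35, 0.35, 0.57 and 0.45 in 2iSB_LIF, in array order. X-linked genes made up 3.99% of tested genes, 8.16% of those higher in 2i_LIF than in LIF_serum and 12.5% of those higher in 2iSB_LIF.

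**Figure D4:**
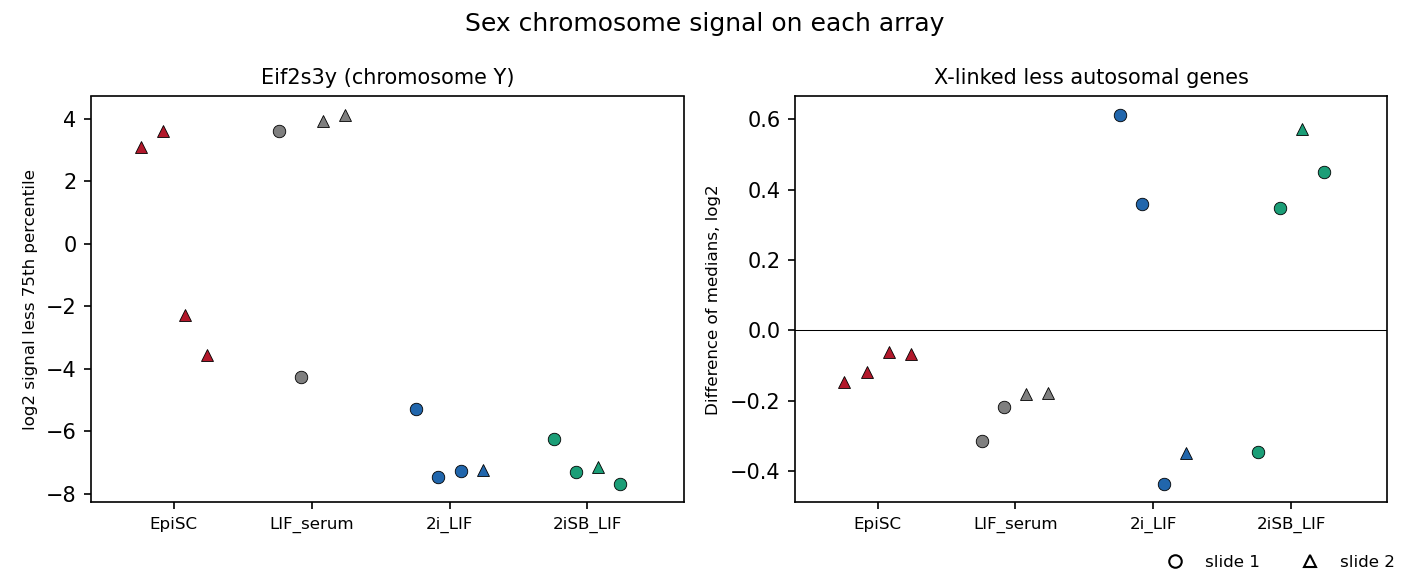
Log2 signal of the Y-linked gene Eif2s3y relative to the array's 75th percentile (left), and median log2 signal of X-linked genes less that of autosomal genes (right), with 1 point per array. Eif2s3y was well above background on none of the 8 ground-state arrays, and 5 of these have X-linked medians between 0.35 and 0.61 while the other arrays lie below 0.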

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

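The contractile gene test, the tests on parts of the ground-state arrays for X-linked signal and the array-wide test of chromosome shifts were chosen only after the result was seen. The second fibroblast list was written after the first had been seen to differ among LIF_serum arrays, and whole-chromosome shifts had been seen before parts of each chromosome were tested. Explanations of the small count between 2iSB_LIF and 2i_LIF by larger spread and by slide had also been drawn up, and their tests were not run. Chance alone sets a sample apart in about 1 in 20 groups, and here 6 of 116 groups of array values and list medians and 9 of 196 groups of gene values had one.

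Fibroblast marker signal differed among LIF_serum arrays and was highest in EpiSC. A candidate explanation is RNA from feeder fibroblasts, which the labels do not name. The descriptions of LIF_serum arrays 1 and 2 carry the code LS and those of arrays 3 and 4 the code LSFF, so the arrays also differ by a code whose meaning is not given. A second list of 24 fibroblast matrix genes had a median 1.63 higher on LIF_serum arrays 1 and 2 than on arrays 3 and 4 (SD over genes 1.90), and 2.87 higher in EpiSC than on LIF_serum arrays 3 and 4 (SD 2.22), values that fit feeder RNA and also cells of the lines that make matrix themselves, which was not tested. Of the 24 genes, 14 to 18 were well above background on ground-state arrays. Slide cannot explain the difference of EpiSC from LIF_serum arrays 3 and 4, since these arrays are all on slide 2. It is not excluded for the difference among LIF_serum arrays, of which arrays 1 and 2 are those on slide 1. The list on slide 1 less slide 2 was at −0.54 in 2i_LIF (SD 0.84) and −0.36 in 2iSB_LIF (SD 1.07), with 1 array of each on slide 2. Neither group was thus higher on slide 1. A bound written beforehand against slide asked for smaller differences in both groups, and the 2i_LIF value missed it. The codes LS and LSFF divide the LIF_serum arrays in the same way, so what they stand for stays open.

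A list of 12 contractile genes was compared in the same way. It was not independent, since Acta2 and Tagln are also in the first fibroblast list and, with Myl9, among the largest falls in 2i_LIF. Their median difference between LIF_serum arrays 1 and 2 and arrays 3 and 4 was −0.48 (SD 1.59), and they were 2.64 higher (SD 2.67) on LIF_serum arrays 3 and 4 than in 2i_LIF. These values do not decide whether feeder RNA caused the contractile differences. No biological explanation was tested.

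Of the Y-linked genes read on each array, Ddx3y, Eif2s3y and Uty, none was well above background on the 8 ground-state arrays, apart from a discarded outlier spot. Lines with 2 active X chromosomes are a candidate explanation for 5 of the 8, whose X-linked medians exceed every LIF_serum array by at least 0.53, and by at least 0.41 in each part of the chromosome. As an explanation for all 8 arrays it failed a bound written beforehand. That bound asked each array to lie above every LIF_serum array with Y-linked signal, and 5 did. The highest X-linked median of the other 3 is −0.35. The arrays were divided into 5 and 3 by this same median, so the values of each part describe them and test nothing. Lines with a single X chromosome and no Y were not tested. Shutdown of Y-linked genes by the medium in male lines is left open. The difference of X-linked from autosomal genes, at least 0.31 in both media, met the bound written beforehand against it, but that bound took no account of the spread of the arrays (SD 0.52 in 2i_LIF and 0.41 in 2iSB_LIF). The sex of the lines is not given in the labels used here.

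Single ground-state arrays had shifts over whole autosomes, of 0.43 for chromosome 8 on 2iSB_LIF array 1, 0.40 for chromosome 8 on 2i_LIF array 4, and 0.40 and 0.35 for chromosomes 2 and 16 on 2iSB_LIF array 4. A candidate explanation is an extra copy of the chromosome in the line, since its parts by gene order and by brightness were raised by 0.28 to 0.50. At most 2 other autosomes of such an array were shifted by 0.1 or more. The bound against an array-wide artefact was set after the shifts had been seen, so it cannot exclude that cause. Of 304 pairs of array and autosome, 8 had a shift of at least 0.2 in size, and the SD of the other shifts was 0.043. Shifts were taken against the mean of the other arrays of the same group, so a raised array lowers the others somewhat. Chromosome 8 on 2i_LIF array 1 and 2iSB_LIF array 2, at −0.25 and −0.21, and chromosome 16 on 2iSB_LIF array 1, at −0.24, lay lower than this alone would give. Chromosome 11 was at −0.25 on LIF_serum array 1, and for none of these lower values was an explanation tested.

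Each count of calls was set against all 35 splits of its 8 arrays. In 5 of the 6 comparisons only 1 split, the real one, gave as many calls. The highest other count was 0 for EpiSC and LIF_serum, 41 for 2i_LIF and LIF_serum, 4 for 2iSB_LIF and LIF_serum, and 0 for both comparisons with EpiSC. A share of 1 in 35 is the smallest this test can give, so chance is unlikely for these but not excluded. The test cannot tell the medium from other traits by which the groups differ. Between 2iSB_LIF and 2i_LIF, 5 splits gave at least the 13 calls of the real one, and the highest other gave 710, so chance cannot be excluded for that count. A split with 710 calls points to a structure of the samples other than the inhibitor, namely 2i_LIF arrays 1 and 2 with 2iSB_LIF arrays 2 and 3 against the rest. The median of X-linked less autosomal genes was 0.61, 0.36, 0.35 and 0.57 on these arrays. It was −0.44 and −0.35 on 2i_LIF arrays 3 and 4, and −0.35 and 0.45 on 2iSB_LIF arrays 1 and 4. Whether X-linked signal underlies the split was not tested.

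On 2i_LIF array 4, 53.3% of probes were well above background, the lowest of its group and apart from it. No other 2i_LIF array is on slide 2. LIF_serum arrays 3 and 4 and 2iSB_LIF array 3, also on slide 2, had 51.58%, 55.36% and 52.96%. Slide 1 arrays had 59.04% to 63.92%, and EpiSC arrays, all on slide 2, had 56.39% to 62.36%. The low value of 2i_LIF array 4 thus cannot be told apart from a difference of slide. The primed epiblast median was 3.09 on EpiSC array 1. The 2-cell-like median was −0.27 on 2i_LIF array 3. Wnt/beta-catenin targets had a median of −0.46 on EpiSC array 1. DNA methylation enzymes had a median of 2.38 on 2iSB_LIF array 2. The epithelial median was 0.49 on 2i_LIF array 4. Crispld1 stood apart at −4.97 on LIF_serum array 3. Eif2s3y stood apart at −5.27 on 2i_LIF array 1 and at −4.26 on LIF_serum array 2. Ffar2 was at −5.57 and Sash3 at −5.75 on LIF_serum array 1. Fgf5 was at 4.42 on EpiSC array 1 and at −0.26 on LIF_serum array 2. Lefty2 was at 6.82 on EpiSC array 4. Pkdcc was at 0.68 on 2iSB_LIF array 4. Of the 16194 probes named only by genome position, 6893 were well above background on all arrays of a group and were not interpreted.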

How the results depend on the processing

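The settings on LIF_serum arrays 3 and 4 or 1 and 2, on X- and Y-linked genes and on genes higher on LIF_serum arrays 1 and 2 were chosen only after the result was seen. No named gene reversed its direction with a call, and no list did so in the camera test, which sets a list against all other genes. Medians of some called lists did turn sign. In EpiSC against LIF_serum these were core pluripotency, oxidative phosphorylation and glycolysis, with median centring. Core pluripotency and oxidative phosphorylation also turned against EpiSC. The ERK feedback median in 2i_LIF turned against LIF_serum arrays 3 and 4 alone. Named genes lost their call in 8 of 1048 values for EpiSC and LIF_serum, 22 of 1152 for 2i_LIF and LIF_serum, 39 of 1148 for 2iSB_LIF and LIF_serum, 56 of 420 for 2iSB_LIF and 2i_LIF, and 2 and 3 of 512 for the comparisons with EpiSC. With an estimated correlation 52 of 150 list results lost their call. The 150 include lists that camera had not called at its preset correlation. Naive pluripotency and germline genes kept their calls in the comparisons of EpiSC with LIF_serum, 2i_LIF and 2iSB_LIF. Nodal/Activin targets kept theirs between 2iSB_LIF and 2i_LIF. Every other list call was lost, including all those in 2i_LIF or 2iSB_LIF against LIF_serum. In the order EpiSC and LIF_serum, 2i_LIF and LIF_serum, 2iSB_LIF and LIF_serum, 2i_LIF and EpiSC, 2iSB_LIF and EpiSC, counts with no minimum fold were 8269, 4685, 5245, 8705 and 8496. With genes well above background on all 16 arrays they were 3362, 1692, 1837, 3644 and 3490, since fewer genes were tested. Slide 1 alone gave 1682 in 2i_LIF and 1756 in 2iSB_LIF against LIF_serum, slide 2 alone gave 4964 in 2iSB_LIF, and passage as a covariate gave 1899 in 2iSB_LIF. The cause of these moves was not tested. In array order, passage numbers were 23, 24, 26 and 26 in LIF_serum and 22, 17, 19 and 24 in 2iSB_LIF. Passage thus differed in part along with medium, and the fit cannot fully tell them apart. Leaving out 1 array gave 4950 to 5162, 2396 to 3007, 2674 to 3421, 5592 to 5957 and 5418 to 5819. Against only LIF_serum arrays 3 and 4 the first 3 counts were 5303, 3571 and 3679, and against only arrays 1 and 2 they were 5316, 2148 and 2439. Without X- and Y-linked genes the 5 counts were 4966, 2708, 2929, 5492 and 5330, and without genes higher on LIF_serum arrays 1 and 2 they were 4480, 2438, 2682, 4911 and 4795. Signal over background limits what dim genes can show, and normexp gave 3952, 1949, 2172, 4427 and 4361.

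The 13 calls between 2iSB_LIF and 2i_LIF moved most. They became 4 at an adjusted p under 0.01, 43 with passage as a covariate, 2 on slide 1, 2232 on slide 2, 3 with only the 8 arrays compared, and 22 with each probe on its own. Leaving out 1 array gave 11 (without 2i_LIF array 3) to 27 (without 2iSB_LIF array 1).

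Line numbers were also put into the fit as a replicate block, which gave 8 calls between 2iSB_LIF and 2i_LIF. Residuals of same-numbered arrays correlated above 0.1 in 7 of 24 pairs, between −0.60 and 0.40, so the numbers do not pair the arrays.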

Other observations

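Calls among probes named only by genome position were counted only after the result for named genes was seen. Between EpiSC and LIF_serum 2323 of 6893 such probes were called, 824 higher and 1499 lower in EpiSC, while called genes were higher in 2780 cases and lower in 2427. What these probes measure was not tested.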
